A study of Homo sapiens with 60 samples.

How the data were processed

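RNA was measured in A549 cells, an established human lung carcinoma line, after 24 h with a herbal extract or with vehicle. Per the labels, 60 libraries fell into 25 groups: vehicle, and 8 extracts at a high, a medium and a low dose. Vehicle had 3 libraries. Yijin-tang (water extract), Liriopis seu Ophiopogonis Tuber, Schisandrae Fructus, Longan Arillus and Zizyphi Semen (ethanol extracts) had 3 libraries per dose, Soshiho-tang (water extract) had 2 per dose, and Polygalae Radix and Aucklandiae Radix (ethanol extracts) had 1 per dose. The doses were 500, 100 and 20 µg/mL, except for Polygalae Radix (380, 76 and 15.2 µg/mL) and Aucklandiae Radix (370, 74 and 14.8 µg/mL). The labels gave the vehicle as 0.1% DMSO, whereas the series design text gave 2%. No DMSO share is recorded for the extract libraries. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. The library labels carried a set number: C1 for vehicle, 8 for Yijin-tang and Soshiho-tang, 9 for Liriopis seu Ophiopogonis Tuber and Schisandrae Fructus, 10 for Longan Arillus and Zizyphi Semen, and 11 for Polygalae Radix and Aucklandiae Radix. Vehicle libraries existed only in set C1.

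Per the labels' protocols, mRNA libraries were made with a directional kit and sequenced on an MGI instrument as 100 bp read pairs. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a, RSEM 1.3.3 and the build hg38 (GRCh38). The annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of expected counts per gene, with no scaling for depth or gene length, for 60675 Ensembl gene identifiers. Of the values, 10.485% were not whole numbers. An official symbol was found for 41209 identifiers, and 57055 were in GENCODE 29, the annotation from which coordinates were taken. RSEM shares reads between near-identical copies, and reads of a gene and its antisense or overlapping neighbour cannot be separated without a known strand setting, so such genes are given as uncertain.

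Expected counts were rounded to whole numbers. The total was 18.003 to 33.832 M counts per library (M, counts in units of 1e6), with a median of 23.897 M, which leaves genes under about 1 count per 1e6 counts (CPM) with few counts. The counts of each pair of libraries of 1 group differed by more than sampling noise (lowest chi-square per degree of freedom 1.863), so each library was counted as a replicate. Values given as CPM were scaled by TMM factors. The error beside a CPM value is the SD over libraries, and the error beside a log2 fold change is its SE.

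The tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined. The 54 libraries of the 19 replicated groups were fitted together with edgeR 4.0.16 (quasi-likelihood F test, robust dispersion, TMM factors, filterByExpr by group) in R 4.3.3. Of the genes, 17826 passed the filter and were tested in 27 contrasts: each dose against vehicle, the high against the low dose of each extract, and the 2 extracts of each set at the high dose. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and every adjusted p of a gene is from this edgeR test unless another tool is named. Groups of 2 or 3 libraries share 1 estimate of the spread in this fit.

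Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) in 15 comparisons, with Benjamini-Hochberg adjustment over the lists of a comparison. Of 33 pathway lists, 32 had at least 3 tested members, and the list of PXR and CAR targets was left out for too few. Members called were counted with adjustment over all genes and adjusted over the list alone. The lists carry the names of regulators or pathways, and their members can also answer to others. Named genes were those called in the same direction against vehicle and against the low dose with a mean of at least 1 CPM, ranked by the smaller of both changes (the first 10 per direction, or where fewer than 5 passed, the first 5 against vehicle alone), up to 4 called members of each called list, and the first 5 per direction between extracts. A gene named outside this rule is said to be so. Results of some genes that the rule names are not reported.

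Polygalae Radix and Aucklandiae Radix had no replicate and no test. Their values are log2 ratios of CPM (with 1 CPM added) to the vehicle mean, and a list's median was placed among the medians of 10000 random lists of equal size matched on expression. The named genes had at least 10 CPM and low, medium and high values in order. Marker lists of 5 other cell types (fibroblast, leukocyte, endothelial, neural and hepatocyte) were summed in each library.

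On simulated data with 200 changed genes and the spread of all 54 libraries, the fit for Soshiho-tang high against vehicle (17583 genes) recovered 46.27% of 1.5-fold, 89.55% of 2-fold and 98.48% of 4-fold changes with 7 false calls. For Schisandrae Fructus high against vehicle (17575 genes), the shares were 76.12%, 95.52% and 98.48%, with 7 false calls. With the spread of the fit without the 2 libraries, they were 95.52%, 98.51% and 100% with 1 false call for Soshiho-tang (17688 genes) and 100%, 98.51% and 100% with 7 false calls for Schisandrae Fructus (17681 genes).

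The alternatives were RLE size factors computed in edgeR, the Wald test of DESeq2 1.42.0, no low-count filter, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, an estimated correlation for the lists, Spearman correlation, a minimum of 10 CPM for correlations, and an added 0.1 CPM for the single libraries. After the data were seen, 2 libraries with few long transcripts were left out (52 libraries, 18228 genes tested), also together with a term for a library batch, and the difference of dose effects between extracts was tested. The planned fit held 54 of the 60 libraries, all but the 6 of Polygalae Radix and Aucklandiae Radix. The series design text names a wortmannin control, which was not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.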

Results

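Gene expression was measured in A549 lung carcinoma cells after 24 h with vehicle or with 1 of 8 herbal extracts at 3 doses, and the series compares each extract with vehicle. Because the vehicle libraries carried their own set number, each high dose was also compared with the low dose of the same extract, which lay in the same set. Library totals ranged from 18.003 to 33.832 M counts. Marker genes of other cell types summed to low levels in the vehicle libraries: 36.0 CPM for fibroblast, 51.5 CPM for neural, 14.8 CPM for leukocyte, 0.874 CPM for hepatocyte and 0.288 CPM for endothelial genes. Over the 60 libraries, these sums ranged from 17.2 to 42.9, 28.6 to 65.3, 4.81 to 32.5, 0.415 to 1.62 and 0.0440 to 0.526 CPM. The sums also differed between doses without overlap: neural sums were 47.46 to 48.94 CPM in Yijin-tang high and 48.94 to 52.67 CPM in Zizyphi Semen high, against 53.58 to 56.21 and 57.08 to 60.94 CPM at their low doses. Fibroblast sums were 39.1 to 40.59 CPM in Liriopis seu Ophiopogonis Tuber high and 36.16 to 36.86 CPM in Schisandrae Fructus high, against 37.28 to 38.81 and 37.11 to 41.98 CPM at their low doses. Mitochondrially encoded mRNA took 11.462% to 11.759% of the counts in the vehicle libraries and up to 18.826% in an extract library (Longan Arillus medium replicate 3).

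A pair of replicated libraries stood apart in transcript length. In Soshiho-tang medium replicate 3 and Longan Arillus low replicate 3, expression relative to the other libraries fell with transcript length, with slopes of -0.4032 and -0.4559 log2 units per doubling of length over 10486 genes, against -0.0806 to 0.0834 in the others. Mitochondrially encoded mRNA was 9.875% and 8.163% of their counts, the lowest shares. They raised the common dispersion of the fit to 0.0173, against 0.00244 without them, so each count of called genes is also given without both, an alternative added after seeing the data.

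**Figure D1:**
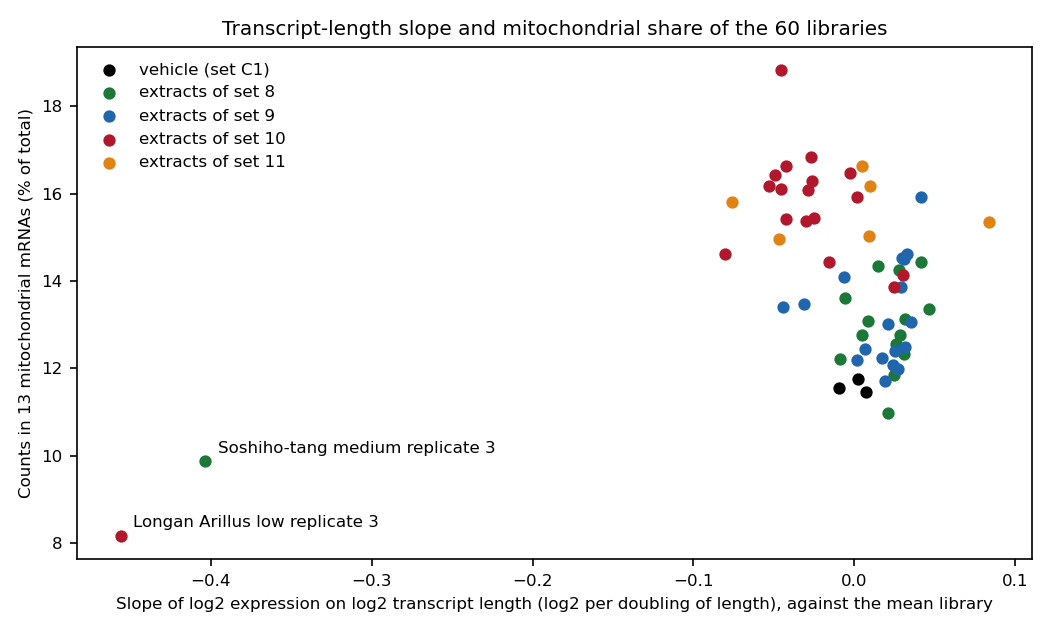
Percentage of counts from mitochondrially encoded mRNA (vertical axis) against the slope of log2 expression on log2 transcript length (horizontal axis), 1 point per library. Soshiho-tang medium replicate 3 and Longan Arillus low replicate 3 lie at slopes of -0.4032 and -0.4559, and the other libraries lie between -0.0806 and 0.0834.

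At 500 µg/mL Soshiho-tang, genes of the ATF4 integrated stress response, the program that cells switch on when translation is restrained or amino acids are short, rose together. STC2, a secreted stress-induced glycoprotein (chromosome 5, 173314713 to 173329503 in GENCODE 29 on GRCh38), reached 68.4 ± 3.72 CPM (n = 2). It was at 20.8 ± 1.03 CPM in vehicle (n = 3) and 16.5 ± 1.9 CPM at the low dose (n = 2). Its log2 fold change was 1.72 ± 0.12, adjusted p = 2.26e-13, against vehicle and 2.05 ± 0.139, adjusted p = 1.82e-13, against the low dose. TRIB3, a pseudokinase induced by ATF4 (chromosome 20, 362835 to 397559), reached 198 ± 7.16 CPM against 61 ± 2.65 CPM in vehicle. DDIT3, the stress transcription factor CHOP, reached 17.8 ± 0.592 against 7.16 ± 0.283 CPM. Of 31 list members tested, 25 rose and 0 fell against vehicle (27 rose adjusted over the list alone; camera adjusted p = 1.38e-95). The low-dose contrast gave 25 higher and 0 lower (25 adjusted over the list alone; camera adjusted p = 6.2e-155). CHAC1, which degrades glutathione, changed by 1.78 ± 0.224 against the low dose. In the fit of 52 libraries, CHAC1 was called lower than vehicle at the low dose of all 4 extracts of sets 8 and 9. Its mean log2 fold change there was -0.959, so the change of 1.78 does not measure a rise over vehicle.

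Chemokine genes of the NF-kB list rose as well, and marker sums of other cell types shifted. The leukocyte sum was 17.58 and 17.96 CPM in the high dose, against 14 to 15.74 CPM in vehicle and 17.11 and 14.94 CPM in the low dose. The fibroblast sum was lower, at 30.75 and 27.61 CPM against 35.59 to 36.77 CPM in vehicle and 37.78 and 37.29 CPM in the low dose. CXCL8, which encodes the neutrophil attractant interleukin 8 (chromosome 4, 73740506 to 73743716), reached 5.2 ± 1.32 CPM in the Soshiho-tang high dose against 1.05 ± 0.398 CPM in vehicle and 0.771 ± 0.0248 CPM at the low dose. CXCL1 changed by 2.39 ± 0.259, adjusted p = 1.77e-08, against vehicle and ICAM1, a leukocyte adhesion receptor, by 1.78 ± 0.235, adjusted p = 1.31e-06. In this list 12 of 18 members rose against vehicle and 9 against the low dose, with 0 lower (16 and 12 adjusted over the list alone). Of 24 genes of the cholesterol list, 15 rose against vehicle and 13 against the low dose, with 0 lower (18 and 18 adjusted over the list alone). An example was INSIG1, a sterol sensor partner (0.90 ± 0.0715 against vehicle). Of 19 genes of the ER unfolded protein response, 8 rose and 0 fell against vehicle (12 adjusted over the list alone), among them the sensor ERN1 (0.99 ± 0.0933), HERPUD1 (0.85 ± 0.108) and the chaperone gene DNAJB9 (0.81 ± 0.143). In the low-dose contrast 5 of these rose (9 adjusted over the list alone). Camera adjusted p values for the NF-kB, cholesterol and unfolded protein lists were 5.7e-27, 1.16e-27 and 7.09e-18 against vehicle and 2.75e-31, 9.13e-45 and 5.03e-18 against the low dose. Targets of the aryl hydrocarbon receptor (AHR), a sensor of planar aromatic compounds, rose in 3 of 7 members against vehicle with 0 lower (3 adjusted over the list alone): the cytochrome P450 genes CYP1A1 (1.82 ± 0.206) and CYP1B1 (1.01 ± 0.0871), and TIPARP (0.88 ± 0.164). Relative to the low dose, 0 were called over all genes (1 adjusted over the list alone; camera adjusted p = 0.0107, higher). CYP1B1 was already at 147.6 and 154.6 CPM at the low dose, against 92.23 to 95.7 CPM in vehicle and 176.8 and 200.9 CPM at the high dose. CYP1A1 was at 2.595 and 3.153 CPM at the low dose, against 0.9751 to 1.47 and 3.268 and 5.046 CPM.

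Heat shock genes, which encode chaperones driven by HSF1, were lower in the Soshiho-tang high dose. HSPA8, the constitutive HSP70 chaperone, was at 1368 ± 2.12 CPM against 1916 ± 23.7 CPM in vehicle, and HSPH1 changed by -0.51 ± 0.0907. HSPA1A changed by -0.81 ± 0.104 and HSPA1B by -0.69 ± 0.101, and the split of reads between these near-identical genes is uncertain. In the list, 0 of 19 rose and 13 fell against vehicle (16 adjusted over the list alone), and 7 fell against the low dose (15 adjusted over the list alone), with camera adjusted p values of 1.31e-26 and 5.66e-25. DNA replication genes (10 of 30 lower against vehicle, 17 adjusted over the list alone) and mitosis genes (5 of 30 lower, 13 adjusted over the list alone) fell, with 0 higher in each, and against the low dose 3 and 5 fell (5 and 6 adjusted over the list alone). Camera adjusted p values were 3.72e-14 and 7.87e-14 against vehicle. Among them were CCNE2, the cyclin of S phase entry (-0.75 ± 0.165), RRM2, a subunit of ribonucleotide reductase (-0.47 ± 0.0836), and CCNB1, the mitotic cyclin (-0.47 ± 0.0603). Proteasome subunit genes fell in 7 of 31 members (8 adjusted over the list alone; camera adjusted p = 3.07e-09), with 0 higher and adjusted p = 0.167 with an estimated correlation.

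The Soshiho-tang high dose had 905 called genes against vehicle (539 higher, 366 lower; 52 and 11 of them by at least 2-fold) and 281 against the low dose (209 higher, 72 lower). Leaving out the 2 libraries that stood apart gave 3920 (1854 higher, 2066 lower) and 1734 (915 higher, 819 lower), so the excess of higher genes was not kept against vehicle. The vehicle count was 294 without high replicate 2 and 382 without high replicate 3. It was 620 to 645 without a vehicle replicate. The low-dose count was 107 and 120 without high replicates 2 and 3, and 97 and 115 without low replicates 2 and 3.

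**Figure D2:**
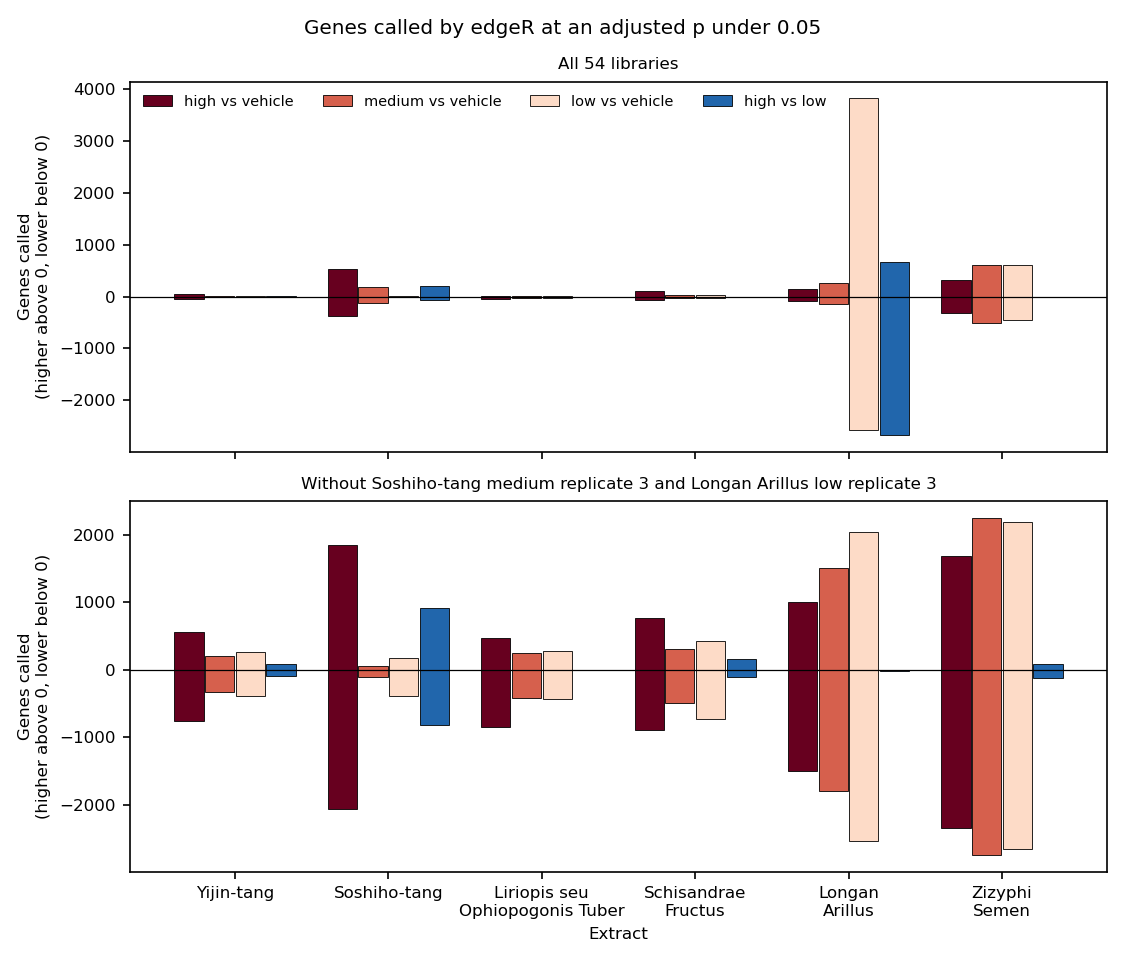
Number of genes called (vertical axis, higher genes upward and lower genes downward), fitted with all 54 libraries and with 52 libraries. Bars show each dose against vehicle and high against low for the replicated extracts. Leaving out 2 libraries raised the Soshiho-tang high count against vehicle from 905 to 3920 and lowered the Longan Arillus high against low count from 3344 to 16.

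Yijin-tang at 500 µg/mL raised genes of the NF-kB list and AHR targets. CXCL1 reached 4.97 ± 0.326 CPM (n = 3) against 0.965 ± 0.229 CPM in vehicle (n = 3), with 2.22 ± 0.143 and 1.36 ± 0.102 CPM at the medium and low doses. Its log2 fold change was 2.35 ± 0.242, adjusted p = 5.47e-08, against vehicle and 1.86 ± 0.238, adjusted p = 7.48e-06, against the low dose. CYP1B1, a cytochrome P450 that oxidizes aromatic hydrocarbons and estrogens (chromosome 2, 38066973 to 38109902 in GENCODE 29 on GRCh38), reached 172 ± 6.57 CPM against 93.7 ± 1.78 CPM in vehicle, and its relative CYP1A1 reached 3.64 ± 0.411 against 1.17 ± 0.265 CPM. TIPARP, an AHR-induced repressor of that receptor, changed by 0.74 ± 0.149. Of 7 AHR targets tested, these 3 rose and 0 fell in both contrasts (3 and 4 adjusted over the list alone; camera adjusted p = 1.06e-16 against vehicle). Of 18 NF-kB genes, 7 rose against vehicle and 5 against the low dose, with 0 lower (11 and 12 adjusted over the list alone), among them CXCL8 (2.12 ± 0.295 against vehicle), CXCL2 (1.11 ± 0.178) and the monocyte attractant CCL2 (1.03 ± 0.153). IL32 (1.06 ± 0.18), an inflammatory cytokine gene, and LCN2 (0.90 ± 0.211), which encodes an iron-binding secreted protein, rose in both contrasts.

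Cholesterol synthesis genes were called in 0 of 24 members against vehicle in edgeR over all genes (8 higher adjusted over the list alone; camera adjusted p = 6.96e-10). Against the low dose, INSIG1 (0.43 ± 0.0658) and MSMO1 (0.41 ± 0.0875), a sterol oxidase, rose (11 adjusted over the list alone; camera adjusted p = 1.2e-29). The fatty acid synthesis genes LPIN1 (0.38 ± 0.0881) and FADS1 (0.28 ± 0.0629) rose against vehicle, 2 of 12 members with 0 lower (4 adjusted over the list alone; camera adjusted p = 1.09e-07). Lower in both contrasts were ID4 (-0.61 ± 0.105 against vehicle) and ID2 (-0.47 ± 0.106), inhibitors of helix-loop-helix transcription factors, ATOH8 (-0.61 ± 0.0668), itself such a factor, and DIO2 (-0.49 ± 0.0786), which activates thyroid hormone.

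The Yijin-tang high dose had 97 called genes against vehicle (51 higher, 46 lower) and 26 against the low dose (18 higher, 8 lower). They were 1307 (554 higher, 753 lower) and 180 (87 higher, 93 lower) without the 2 libraries that stood apart. The vehicle count was 54, 62 and 53 without vehicle replicates 1 to 3 and 57, 69 and 57 without high replicates 1 to 3. The low-dose count was 15 and 16 without low replicates 1 and 2, 17 without high replicate 3, and 18 to 20 without the remaining libraries.

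At the high dose, stress response genes separated the mixtures of set 8: CHAC1 was at 4.03 ± 0.193 CPM in Yijin-tang (n = 3) and 14.5 ± 0.196 CPM in Soshiho-tang (n = 2), a log2 difference of -1.85 ± 0.199, adjusted p = 2.93e-08. STC2 differed by -1.60 ± 0.121, FOSB, an immediate early transcription factor, by -2.31 ± 0.308, and ADM2, a secreted peptide hormone, by -1.90 ± 0.236. Of 31 ATF4 genes, 22 were lower in Yijin-tang and 0 higher (25 adjusted over the list alone; camera adjusted p = 4.6e-161). Immediate early genes (6 of 17 lower, 9 adjusted over the list alone), cholesterol genes (6 of 24 lower, 11 adjusted over the list alone) and p53 targets (5 of 25 lower, 10 adjusted over the list alone) had 0 members higher in Yijin-tang. Their camera adjusted p values were 6.43e-24, 7.87e-19 and 3.67e-19. Heat shock genes were higher in Yijin-tang in 7 of 19 members with 0 lower (14 adjusted over the list alone), as were 5 of 30 mitosis genes (6 adjusted over the list alone). HSPA8 differed by 0.52 ± 0.0665 and CCNB1 by 0.32 ± 0.0602. Among NF-kB genes, ICAM1 was lower in Yijin-tang (-0.89 ± 0.23, adjusted p = 0.0373), 1 of 18 members (3 adjusted over the list alone). The marker sums of other cell types differed as well: leukocyte sums were 14.37, 13.81 and 15.32 CPM in Yijin-tang against 17.58 and 17.96 CPM in Soshiho-tang, and fibroblast sums 37.16, 34.19 and 34.42 against 30.75 and 27.61 CPM. The count was 213 genes (58 higher and 155 lower in Yijin-tang), or 1526 (706 higher and 820 lower) without the 2 libraries that stood apart. It was 70 and 103 without Soshiho-tang high replicates 2 and 3 and 138, 133 and 150 without Yijin-tang high replicates 1 to 3.

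**Figure D3:**
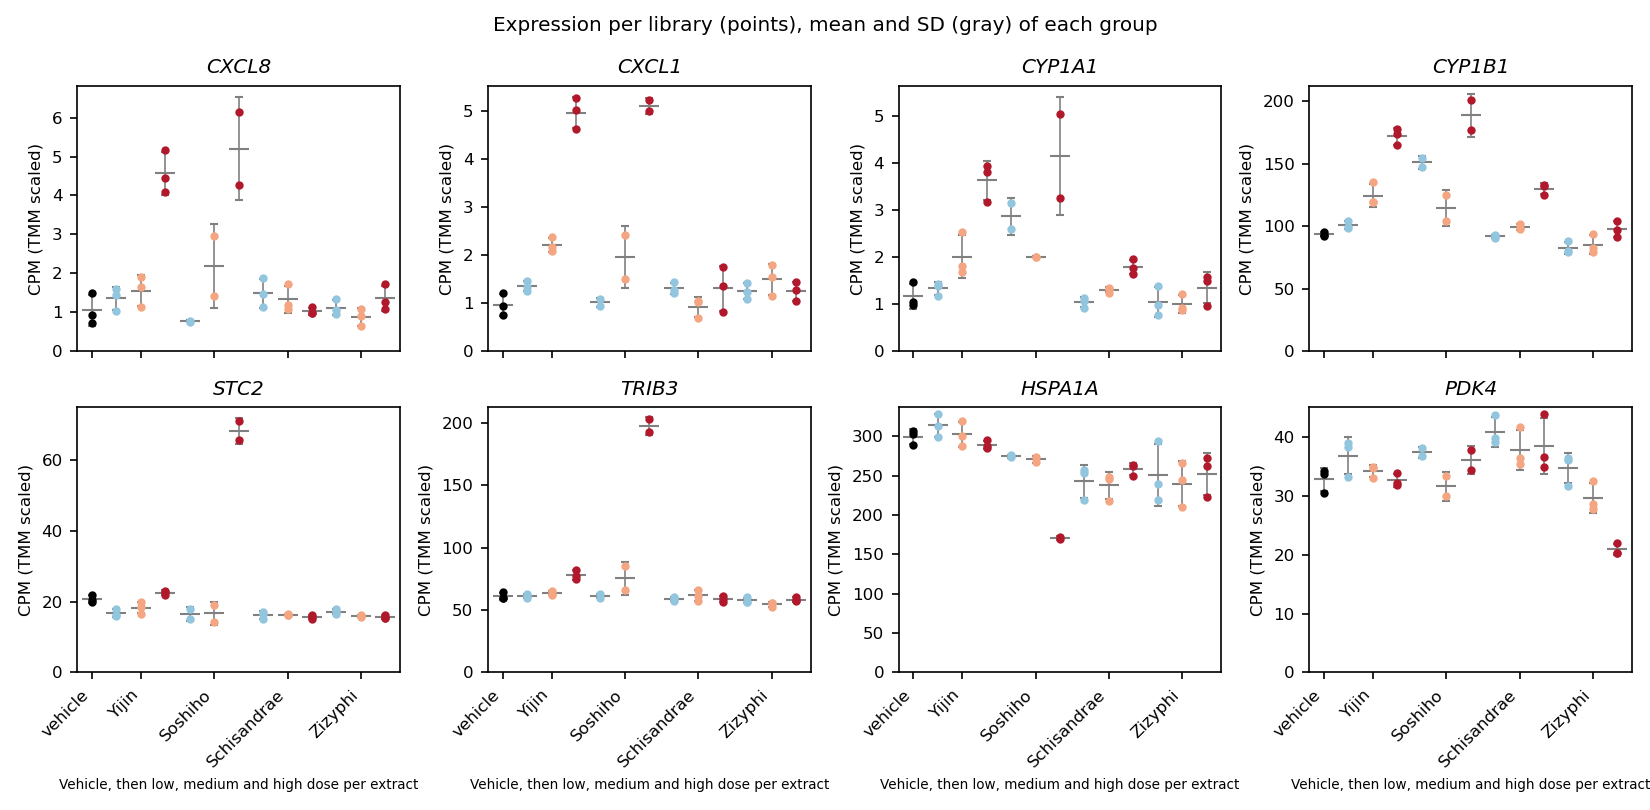
CPM per library (linear vertical axis) of CXCL8, CXCL1, CYP1A1, CYP1B1, STC2, TRIB3, HSPA1A and PDK4 in vehicle and at the low, medium and high dose of 4 extracts, with the mean and SD in gray. STC2 reached 68.4 CPM in the Soshiho-tang high dose (n = 2) against 20.8 CPM in vehicle (n = 3).

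Schisandrae Fructus at 500 µg/mL raised CYP1B1 to 129.9 ± 4.4 CPM (n = 3), against 93.7 ± 1.78 CPM in vehicle (n = 3) and 91.9 ± 1.27 CPM at the low dose (n = 3). Its log2 fold change was 0.47 ± 0.0792, adjusted p = 0.000531, against vehicle and 0.50 ± 0.0793, adjusted p = 0.0037, against the low dose. Of 7 AHR targets it was the member called in both contrasts, with 0 lower (3 and 3 higher adjusted over the list alone). The list was higher with camera adjusted p = 0.000612 and 1.02e-11. Against vehicle, HMOX1, which degrades heme (0.28 ± 0.0653), and GCLC, which makes glutathione (0.16 ± 0.0353), rose among 28 NRF2 targets with 0 lower (2 adjusted over the list alone), with adjusted p = 0.232 with an estimated correlation. Against the low dose, 0 of these 28 were called over all genes (1 adjusted over the list alone; camera adjusted p = 3.51e-06, higher). ANGPTL4 (0.46 ± 0.107), a lipase inhibitor, and BNIP3L (0.33 ± 0.0632), a mitophagy receptor, rose against vehicle, 2 of 20 hypoxia genes with 0 lower (5 adjusted over the list alone; camera adjusted p = 0.000221, and 2.6e-05 against the low dose).

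In Schisandrae Fructus, INSIG1 changed by -0.28 ± 0.0654, adjusted p = 0.0222, against vehicle (n = 3 each). In the cholesterol list 2 of 24 members fell and 0 rose against vehicle (4 adjusted over the list alone). In the low-dose contrast 0 were called over all genes or over the list, where the list was lower with camera adjusted p = 2.6e-05. Of 14 FOXO targets, FBXO32 (0.63 ± 0.156), a ubiquitin ligase of muscle atrophy, and CCNG2 (0.60 ± 0.11), an atypical cyclin, rose against vehicle with 0 lower (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.26e-05). Relative to the low dose 0 were called (1 higher adjusted over the list alone), with adjusted p = 0.278 with an estimated correlation. Schisandrae Fructus high had 181 called genes against vehicle (107 higher, 74 lower) and 1 against the low dose, CYP1B1 (655 genes at an unadjusted p under 0.05; 21 by DESeq2). The counts were 1667 (771 higher, 896 lower) and 280 (166 higher, 114 lower) without the 2 libraries that stood apart. Leaving out 1 library gave 69, 90 and 67 genes against vehicle without vehicle replicates 1 to 3 and 85, 85 and 101 without high replicates 1 to 3. The low-dose count was 0 without low replicate 1 and 1 without each of the others.

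Liriopis seu Ophiopogonis Tuber at 500 µg/mL had no gene called against its low dose in edgeR (279 genes at an unadjusted p under 0.05; 1 gene by DESeq2; 0 without the 2 libraries that stood apart). The AHR list was higher at the high dose with camera adjusted p = 7.26e-05, with 0 of 7 members called over all genes and 2 adjusted over the list alone. CYP1B1, named here after its values were seen, was at 108 ± 1.06 CPM against 90.5 ± 1.66 CPM at the low dose. The cholesterol list was lower with camera adjusted p = 0.00336 and 0 of 24 members called over all genes or over the list. Against vehicle, 57 genes were called (21 higher, 36 lower), or 1326 without the 2 libraries that stood apart. Lower genes included BTG2, an antiproliferative p53 target (-0.86 ± 0.086, adjusted p = 4.48e-08), CHAC1 (-0.93 ± 0.187), SESN2, a stress-induced inhibitor of mTORC1 (-0.69 ± 0.0867), and DDIT4 (-0.48 ± 0.0687). These falls were not particular to this extract or dose. Without the 2 libraries that stood apart, BTG2, CHAC1, SESN2 and DDIT4 were called lower than vehicle at the low dose of all 4 extracts of sets 8 and 9. Their mean log2 fold changes there were -0.789, -0.959, -0.512 and -0.34. In the ATF4 list, 4 of 31 fell and 0 rose (6 adjusted over the list alone; camera adjusted p = 7.73e-10). In the p53 list 3 of 25 fell and 0 rose (6 adjusted over the list alone; camera adjusted p = 4.78e-12). The vehicle count was 31, 27 and 28 without vehicle replicates 1 to 3 and 27, 46 and 29 without high replicates 1 to 3. The low-dose count was 0 with any 1 library left out.

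Compared directly at the high dose, Schisandrae Fructus exceeded Liriopis seu Ophiopogonis Tuber in CYP26B1, which degrades retinoic acid (log2 difference -0.65 ± 0.121, adjusted p = 0.0138; n = 3 each), CACNG6, a calcium channel subunit (-0.53 ± 0.0968), TMEM156 (-0.48 ± 0.0867), CHKA, a choline kinase (-0.35 ± 0.0746), and TFPI, an inhibitor of coagulation (-0.32 ± 0.0641). MT-RNR1, a mitochondrial ribosomal RNA, was higher in Liriopis seu Ophiopogonis Tuber (0.46 ± 0.0866). The hypoxia, NRF2 and AHR lists were lower in Liriopis seu Ophiopogonis Tuber, with camera adjusted p values of 1.98e-05, 1.98e-05 and 0.00867, and 0 of their 20, 28 and 7 members were called over all genes (4, 1 and 1 lower adjusted over the list alone). The count was 10 genes (1 higher, 9 lower; 796 at an unadjusted p under 0.05; 35 by DESeq2), or 542 without the 2 libraries that stood apart. Leaving out 1 library gave 0, 0 and 1 genes without Liriopis seu Ophiopogonis Tuber high replicates 1 to 3 and 0, 1 and 2 without Schisandrae Fructus high replicates 1 to 3.

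Zizyphi Semen at 500 µg/mL lowered PDK4, the kinase that turns off pyruvate dehydrogenase (chromosome 7, 95583499 to 95596491 in GENCODE 29 on GRCh38), to 20.9 ± 0.989 CPM (n = 3). It was at 32.9 ± 1.99 CPM in vehicle (n = 3), 29.7 ± 2.54 CPM at the medium and 34.8 ± 2.62 CPM at the low dose. Its log2 fold change was -0.65 ± 0.0884, adjusted p = 1.53e-05, against vehicle and -0.73 ± 0.0888, adjusted p = 8.58e-06, against the low dose. PTGS2, the inducible cyclooxygenase, fell in both contrasts to 18.4 ± 1.92 CPM from 29.2 ± 1.92 CPM in vehicle, as did FAM107B (-0.23 ± 0.0427). With a term for a library batch added, PTGS2 was no longer called against vehicle (adjusted p = 0.101). FA2H, a fatty acid hydroxylase of sphingolipid synthesis, rose in both contrasts to 27.2 ± 1.42 from 20.9 ± 1.14 CPM, and the adhesion gene CDH4 to 32.4 ± 0.821 from 26.4 ± 0.851 CPM. These were the 5 genes called against the low dose. Of 13 mitochondrially encoded mRNAs, 10 rose against vehicle and 0 fell (11 adjusted over the list alone; camera adjusted p = 1.34e-16), such as MT-ND1, a complex I subunit (0.83 ± 0.141). Of these, 0 were called against the low dose over all genes or over the list alone. With the library batch term and without the 2 libraries, the list had camera adjusted p = 1.88e-06, higher, and MT-ND1 a log2 fold change of 0.70 (adjusted p = 0.0296). The same list had a median log2 ratio of 0.508 in Aucklandiae Radix high, of set 11, against vehicle and -0.0504 against its low dose (1 library each). In Polygalae Radix high, also of set 11, these medians were -0.000815 and -0.536 (1 library each). SNAI2, a repressor of epithelial genes (1.17 ± 0.306), and BHLHE40 (0.50 ± 0.139) rose among 17 mesenchymal genes with 0 lower (3 adjusted over the list alone), with adjusted p = 0.421 with an estimated correlation. BHLHE40 was also called higher than vehicle at the low dose of all 4 extracts of sets 8 and 9. There its mean log2 fold change was 0.368, in the fit without the 2 libraries that stood apart. Relative to the low dose of Zizyphi Semen, the NF-kB and cholesterol lists were higher with camera adjusted p = 2.19e-06 and 1.19e-05 and 0 of 18 and 0 of 24 members called over all genes (1 and 0 adjusted over the list alone). The leukocyte marker sum moved with this change, at 21.45, 20.37 and 20.05 CPM in the high dose, 15.81, 17.80 and 18.24 CPM in the low dose and 14 to 15.74 CPM in vehicle.

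Among the genes named for Zizyphi Semen against vehicle alone, several have uncertain counts. The pseudogene MALLP1 (5.43 ± 1.5), MTND5P11 (1.72 ± 0.384), a nuclear copy of a mitochondrial gene, the antisense genes SLC7A11-AS1 (-4.10 ± 0.805) and BDNF-AS (-2.76 ± 0.421), and ZBED6, which lies inside another gene (-2.85 ± 0.843), share reads or positions with other genes. With the library batch term, BDNF-AS was still called, MALLP1, MTND5P11 (0.26) and SLC7A11-AS1 (-0.30) were not, and ZBED6 turned to 1.27 with no call. Against vehicle 653 genes were called (328 higher, 325 lower) and against the low dose 5 (669 at an unadjusted p under 0.05; 19 by DESeq2). The counts were 4034 (1693 higher, 2341 lower) and 210 (82 higher, 128 lower) without the 2 libraries that stood apart, and 925 and 306 with a term for a library batch added. Leaving out 1 library gave 273, 304 and 227 genes against vehicle without vehicle replicates 1 to 3 and 285, 278 and 281 without high replicates 1 to 3. The low-dose count was 3 and 2 without low replicates 1 and 3, 2 without high replicate 2 or 3, and 5 without the remaining libraries.

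Longan Arillus at 500 µg/mL gave 3 genes called in both contrasts: PLEK2, a cytoskeletal protein, was higher (0.45 ± 0.117, adjusted p = 0.0389, against vehicle; n = 3 each), and CHAC1 (-0.75 ± 0.184) and SLC2A3, a glucose transporter (-0.39 ± 0.0589), were lower. In the fit without the 2 libraries that stood apart, these 3 were called against vehicle and not against the low dose (adjusted p = 0.266, 0.858 and 0.140). Against vehicle 237 genes were called (150 higher, 87 lower), among them SGPP2, a sphingosine phosphate phosphatase (1.31 ± 0.264), which was called in the same direction in Liriopis seu Ophiopogonis Tuber and Zizyphi Semen against the same vehicle libraries. SGPP2 was also called higher than vehicle at the low dose of all 4 extracts of sets 8 and 9. There its mean log2 fold change was 0.955, in the fit without the 2 libraries that stood apart. Of 25 p53 targets, 4 fell in Longan Arillus high against vehicle and 0 rose (4 adjusted over the list alone; camera adjusted p = 3.76e-09), such as BTG2 (-0.63 ± 0.0849) and MDM2, the ubiquitin ligase of p53 (-0.27 ± 0.0524). Against the low dose 3344 genes were called (676 higher, 2668 lower). Of oxidative phosphorylation genes 36 of 50 were lower and 2 higher, and of ribosomal protein genes 50 of 70 were lower and 0 higher (40 and 61 adjusted over the list alone; camera adjusted p = 5.69e-08 and 7.86e-14, and adjusted p = 0.857 for both with an estimated correlation). The low-dose group held replicate 3, which stood apart, and without that library 3 genes were called. Without the 2 libraries that stood apart the count was 16, 7 of them called in both fits. In that fit 0 members of those lists were called (edgeR), and both lists were higher instead (camera adjusted p = 3.8e-05 and 0.000608, and adjusted p = 0.718 for both with an estimated correlation). With 1 other library left out, the low-dose count was 7659 and 7537 without low replicates 1 and 2 and 282, 1566 and 2145 without high replicates 1 to 3. For vehicle, the count was 94, 108 and 83 without vehicle replicates 1 to 3 and 576, 56 and 59 without high replicates 1 to 3. It was 2516 (1011 higher, 1505 lower) without the 2 libraries that stood apart and 692 (235 higher, 457 lower) with a library batch term added, so the larger direction turned.

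Between both extracts of set 10 at the high dose, PDK4 was higher in Longan Arillus (0.67 ± 0.0888, adjusted p = 7.37e-05; n = 3 each) and FA2H was lower (-0.40 ± 0.0679, adjusted p = 0.00711). These were the 2 genes called (554 at an unadjusted p under 0.05; 15 by DESeq2; 131 called without the 2 libraries that stood apart). The hypoxia, cholesterol and NF-kB lists were lower in Longan Arillus with camera adjusted p values of 0.000157, 0.000495 and 0.00734, and 0 of their 20, 24 and 18 members were called over all genes or over the list alone. The leukocyte marker sum differed too, at 15.32, 17.24 and 14.5 CPM in Longan Arillus and 21.45, 20.37 and 20.05 CPM in Zizyphi Semen. The count was 1, 2 and 1 without Longan Arillus high replicates 1 to 3 and 2, 2 and 1 without Zizyphi Semen high replicates 1 to 3.

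**Figure D4:**
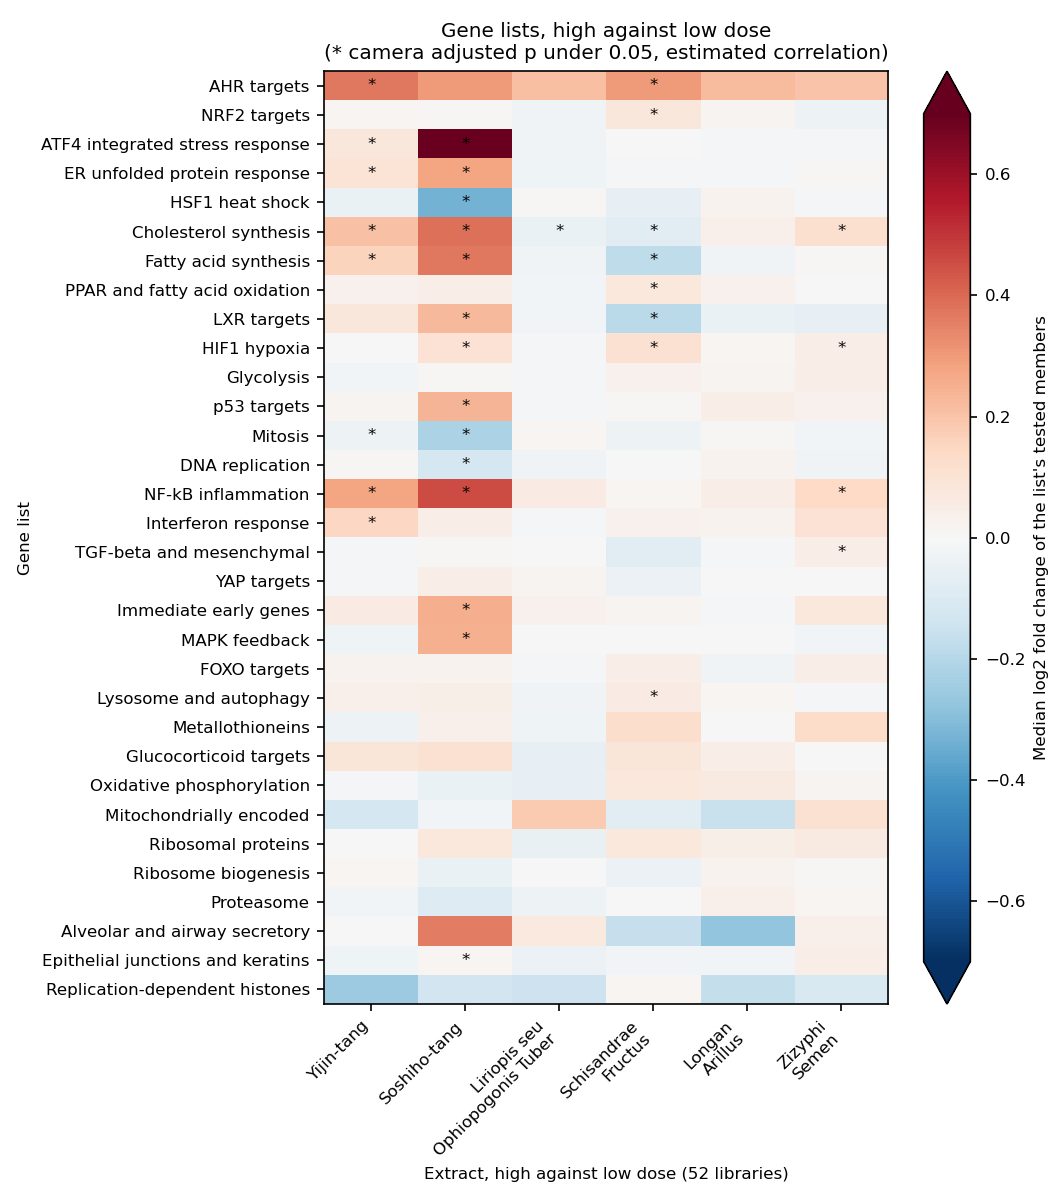
Median log2 fold change of each gene list in the high against the low dose (color) for 6 extracts, fitted with 52 libraries, where an asterisk marks camera adjusted p below 0.05 with an estimated correlation. In Soshiho-tang, 28 of the 31 ATF4 genes were called higher in this fit.

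BTG2, the antiproliferative p53 target, was called lower than vehicle in the high dose of all 6 replicated extracts. It was at 11.8 ± 0.678 CPM in vehicle (n = 3), 7.39 ± 0.191 and 6.95 ± 0.154 CPM at the high and low doses of Yijin-tang, and 6.72 ± 0.39 and 6.86 ± 0.459 CPM at those of Schisandrae Fructus (n = 3 each). AMOTL2, a target and inhibitor of the growth regulator YAP, was at 112 ± 2.91 CPM in vehicle and 78 ± 1.48 CPM at the low dose of Yijin-tang. In the YAP list, AMOTL2, NUAK2, ANKRD1 and CCN2 fell in Yijin-tang high against vehicle, 4 of 22 with 0 higher (8 lower and 2 higher adjusted over the list alone; camera adjusted p = 1.46e-08). KLF2, a transcription factor, was higher, at 10.2 ± 1.63 CPM in the low dose of Yijin-tang against 6.07 ± 0.727 CPM. Without the 2 libraries that stood apart, 74 genes were higher and 156 lower than vehicle at the low dose of all 4 extracts of sets 8 and 9. Between Yijin-tang and Soshiho-tang at the low dose, 99 higher and 208 lower genes were shared, against 2.44 and 8.39 for independent lists. Contrasts with the same vehicle libraries share their noise: over 12 pairs of extracts of different sets, the covariance of low-dose fold changes was 0.0141, against 0.00378 simulated for unchanged groups, and the correlation 0.564 against 0.452. The vehicle libraries are the only ones of their set, so the set and the treatment cannot be told apart in any comparison with vehicle.

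At the medium and low doses, the mean levels of CYP1B1 and CXCL8 in Yijin-tang lay between vehicle and the high dose. CYP1B1 was at 101 ± 3.27, 125 ± 9.28 and 172 ± 6.57 CPM at the low, medium and high dose (n = 3 each), and CXCL8 at 1.36 ± 0.29, 1.56 ± 0.4 and 4.57 ± 0.557 CPM. In Soshiho-tang, STC2 was at 16.5 ± 1.9 and 16.7 ± 3.21 CPM at the low and medium dose (n = 2 each), the latter with the library that stood apart. CYP1B1 was not in dose order there, at 147.6 and 154.6 CPM at the low and 124.8 and 104.5 CPM at the medium dose. CXCL8 was at 0.7533 and 0.7884 CPM at the low and 1.43 and 2.958 CPM at the medium dose of Soshiho-tang, against 0.735 to 1.497 CPM in vehicle. Against vehicle, Yijin-tang had 18 called genes at the medium and 26 at the low dose, Liriopis seu Ophiopogonis Tuber 39 and 33, Schisandrae Fructus 58 and 61, Zizyphi Semen 1115 and 1067, Longan Arillus 410 and 6397, and Soshiho-tang 311 and 8. Without the 2 libraries that stood apart, the counts were 525 and 658, 667 and 709, 786 and 1157, 4990 and 4861, 3306 and 4583, and 172 and 557 in that order. In that fit the medium dose of Soshiho-tang held 1 library, so its 172 rests on the spread of the other groups and has no replicate check. Of the genes called in Soshiho-tang medium, 30 were called in both fits, and of those in Longan Arillus low, 2769. With a library batch term, the counts were 1330 and 1041 for Zizyphi Semen and 1313 and 847 for Longan Arillus.

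With vehicle replicates 1 to 3 and then the replicates of the dose left out in turn, the medium-dose counts were 7, 4, 3, 6, 5 and 5 for Yijin-tang, 16, 24, 21, 15, 25 and 25 for Liriopis seu Ophiopogonis Tuber, 31, 37, 35, 31, 38 and 38 for Schisandrae Fructus, 180, 207, 141, 798, 170 and 83 for Longan Arillus, and 600, 709, 513, 667, 503 and 768 for Zizyphi Semen. The low-dose counts were 4, 7, 3, 3, 9 and 5, then 27, 28, 28, 28, 25 and 23, then 39, 38, 31, 30, 38 and 35, then 4685, 4913, 4629, 8889, 8864 and 2471, and then 605, 595, 524, 650, 465 and 617 for these extracts. Soshiho-tang had 83, 88 and 67 genes at the medium dose without vehicle replicates 1 to 3, 7983 without medium replicate 2 and 4 without medium replicate 3, which stood apart. Its low dose had 4, 5 and 5 without the vehicle replicates and 4 and 2 without low replicates 2 and 3.

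Over the 15 pairs of extracts, the correlation of high-against-low log2 fold changes across 17826 genes had a median of 0.0232 (-0.0593 to 0.0832), where genes are not independent replicates. Among genes of at least 10 CPM it ranged from -0.212 to 0.362. Without the 2 libraries that stood apart, over all tested genes, the median was 0.00889 (-0.053 to 0.0722).

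Polygalae Radix and Aucklandiae Radix had 1 library per dose, so their values have no replicate check. In the Polygalae Radix high library (380 µg/mL), 1635 of 10009 genes differed at least 2-fold from the vehicle mean (348 higher, 1287 lower), against 60 at the medium and 25 at the low dose. Each vehicle library differed from the others in 1. This library stood apart too: its best correlation with any other library was 0.9424 and its median 0.8994, against 0.9453 and 0.9258 in Soshiho-tang medium replicate 3. Its summed markers of fibroblasts, leukocytes and neural cells were 17.2, 4.81 and 28.6 CPM, against 36, 14.8 and 51.5 CPM in vehicle, and a technical cause was not excluded. The nuclear receptor genes NR4A2 and NR4A3 had log2 ratios of 2.90 and 2.84, and NEAT1, a nuclear long noncoding RNA, was at 1258 CPM against 294 ± 10.9 CPM in vehicle (n = 3). NEAT1 was already at 529.9 CPM at the low and 676.5 CPM at the medium dose. Its log2 ratio was 2.09 to vehicle and 1.25 to the low dose, and those of NR4A2 and NR4A3 to the low dose were 2.44 and 2.56. Set 11 held no vehicle library, so ratios to vehicle also cross library sets. PHGDH, which starts serine synthesis (log2 ratio -3.44), ALDH3A1, an aldehyde dehydrogenase (-3.36), the keratin KRT8 (-2.92), the chaperone HSP90AA1 (-2.89) and ASNS, asparagine synthetase (-2.89), were lower. Glycolysis genes had a median of -1.71 (13 of 18 lower by at least 2-fold, 0 higher), a median below all 10000 random lists. The proteasome (-1.27; 24 of 31 lower), oxidative phosphorylation (-1.21; 36 of 50 lower) and mesenchymal lists (-1.54; 11 of 17 lower) were also below all of them, with 0 members higher by that much. The median of immediate early genes was 0.589 (percentile 99.99; 7 of 17 higher, 1 lower). Relative to the low dose of the same set, the medians of these 5 lists were -1.51, -1.06, -0.933, -1.43 and 0.69.

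In the Aucklandiae Radix high library (370 µg/mL), 148 of 9811 genes differed at least 2-fold (69 higher, 79 lower), against 62 at each lower dose. Its leukocyte marker sum was 32.5 CPM, the highest of the 60 libraries, against 14.8 CPM in vehicle and 16.5 CPM at the low dose, while the neural sum was 29.7 against 51.5 CPM and the fibroblast sum 25.1 against 36 CPM in vehicle. HMOX1 was at 522 CPM against 152 ± 1.47 CPM in vehicle, and BIRC3, an apoptosis inhibitor of the NF-kB pathway, and ANGPTL4 had log2 ratios of 1.63 and 1.51. The keratin KRT4 (-2.64), the synaptic gene CPLX2 (-2.05), the cytokine IL11 (-1.85) and the tight junction gene CLDN2 (-1.79) were lower. Mitosis genes had a median of -0.76 (30 of 30 below the vehicle mean, 5 by at least 2-fold), heat shock genes -0.53 and cholesterol genes -0.43, each below all 10000 random lists. The p53 targets had a median of 0.32 (21 of 25 above the vehicle mean, 0 by 2-fold), above all random lists, and AHR targets a median of 0.49 (percentile 99.84; 2 of 7 higher by at least 2-fold). Against the low dose, which lay in the same set, the medians were -0.626, -0.459, -0.354, 0.513 (24 of 25 above 0, 1 by 2-fold) and 0.845 for these 5 lists. KRT87P and FER1L4 were named by the rule but are pseudogenes, and the antisense gene CHMP1B-AS1 of Polygalae Radix overlaps another gene, so their ratios of -1.61, 1.64 and 2.30 are uncertain.

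**Figure D5:**
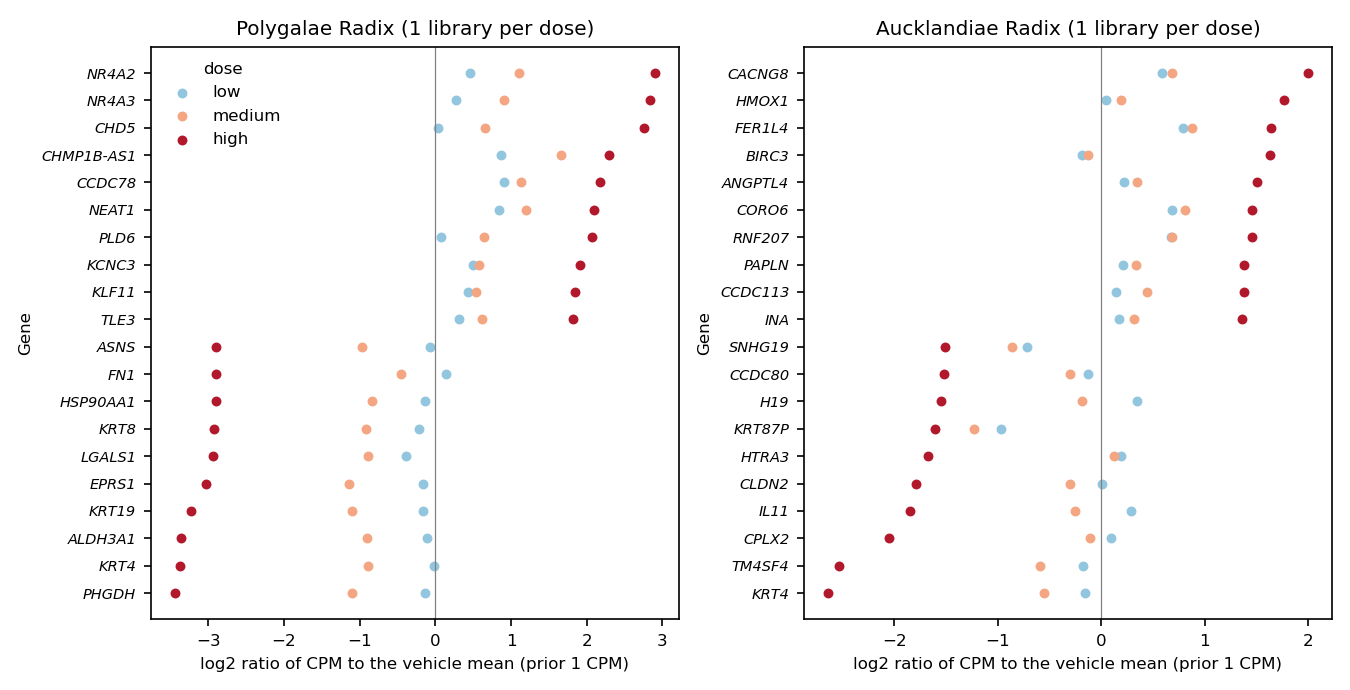
Log2 ratio of CPM to the vehicle mean (horizontal axis) of the genes named for Polygalae Radix and Aucklandiae Radix at 3 doses, 1 library per dose with no replicate. In the Polygalae Radix high library PHGDH was at -3.44 and NR4A2 at 2.90.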

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

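The tests of the libraries that stood apart, of the library batch, of the vehicle library set and of the differences between dose effects were chosen after the results were seen. The tests of the shared vehicle noise and of a response growing with dose, and the splits of the libraries, were written before their results. The following of shared genes from low to high dose, and the reading of the response growing with dose by the spread of its pairs and by these genes, were added after the results were seen.

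Each result of the next 3 paragraphs was brought up by a tested difference between extracts of the same set. Yijin-tang and Soshiho-tang differed at the high dose in 213 genes. Higher in Yijin-tang were CBLN2, a synapse organizer (log2 difference 1.002), HSPA1B (0.7683) and HSPA1A (0.7599), whose shared reads leave their split uncertain, BCO1, which cleaves carotenoids (0.6758), and BAAT, which conjugates bile acids (0.6472). Higher in Soshiho-tang were FOSB (-2.314), ADM2 (-1.899), CHAC1 (-1.846), STC2 (-1.599) and EGR1, an immediate early transcription factor (-1.379). The change from low to high dose differed between these mixtures in 51 genes, 46 of them larger in Soshiho-tang, and in 471 without the 2 libraries that stood apart (177 larger in Yijin-tang, 294 in Soshiho-tang).

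Liriopis seu Ophiopogonis Tuber and Schisandrae Fructus differed at the high dose in 10 genes: MT-RNR1 was higher in the former (0.4613), and CYP26B1 (-0.6461), CACNG6 (-0.5268), TMEM156 (-0.4837), CHKA (-0.3543) and TFPI (-0.3247) were among the 9 higher in the latter. The change from low to high dose differed in 58 genes without the 2 libraries, and in 0 by edgeR with all libraries (481 at an unadjusted p under 0.05).

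Longan Arillus and Zizyphi Semen differed at the high dose in 2 genes, PDK4 (0.6698) and FA2H (-0.399). The change from low to high dose differed in 2 genes with all libraries and in 25 without the 2 libraries that stood apart.

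Soshiho-tang medium replicate 3 and Longan Arillus low replicate 3 stood apart from the other libraries. Against RNA of these 5 other cell types, their summed markers reached at most 1.07 times the highest of the other libraries (fibroblast, leukocyte, endothelial, neural and hepatocyte lists). Cells outside these lists, such as another epithelial line, were not looked for. How a loss of long transcripts changes such sums was not tested, so RNA of other cells is not excluded. Against an effect of the extract, the other replicates of the same groups had length slopes down to -0.0496, within the range of the remaining libraries (-0.0806 to 0.0834). Their slopes of -0.4032 and -0.4559 describe a loss of long transcripts. The same slopes set these libraries apart, so they give no separate support for that loss as the explanation. What led to such a loss stays open.

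Library sets 10 and 11 stood apart from vehicle and sets 8 and 9. Positions along the difference between Zizyphi Semen low and vehicle were measured from the mean of the low-dose libraries of set 9. Within Longan Arillus, replicate 1 of the high and medium doses lay near those low doses, at 0.047 and 0.103 of the slope of replicates 2 and 3. Its distance from vehicle was not measured. These ratios argue against an effect of the extracts as the whole cause. A library batch may be a source of the difference, since replicates 2 and 3 minus replicate 1, libraries of the same extract and dose, correlated with it across genes at 0.591 (high) and 0.677 (medium). With a batch term, the Zizyphi Semen high count against vehicle was 925, against 4034 without the term, in fits without the 2 libraries. The term rests only on replicate 1 against replicates 2 and 3 of Longan Arillus high and medium, chosen from the data. Its uncertainty enters each Zizyphi Semen contrast with vehicle, so the fall in calls does not measure the share of a batch. Effects of Zizyphi Semen, whose libraries all lie in that batch, stay open beside it.

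Low doses of each replicated extract differed from vehicle in genes shared between extracts. Noise of the shared vehicle libraries, simulated at the spread between libraries of a group, falls short. The covariance was 3.73 times the simulated value (0.0141 against 0.00378, highest of 20 simulations 0.00452). The simulation holds no deviation common to all vehicle libraries. Since replicates may not be separate cultures, such a deviation stays open. A common response that grows with dose stays open: the low-dose change of 1 extract and the high-against-low change of another had a median correlation of -0.118 over 30 ordered pairs, under the bound of 0.05 set in advance, but they spread from -0.584 to 0.251. Of genes called alike in the low dose of 3 extracts of sets 8 and 9, 62.6% of 348 in Soshiho-tang and 66.4% of 277 in Liriopis seu Ophiopogonis Tuber moved on in the same direction from low to high in the fourth (63 and 0 called, 37 and 0 opposite; medians 0.0459 and 0.0264, against 0.209 and 0.203 for low against vehicle), and 48.4% of 273 in Yijin-tang and 39.1% of 243 in Schisandrae Fructus (2 and 7 called, 6 and 8 opposite; medians -0.00191 and -0.0279). The library set of the vehicle and a response already complete at the low dose cannot be told apart for the 230 genes called alike in sets 8 and 9, because no vehicle library lies in another set. The DMSO share of the extract libraries is not recorded, so a solvent difference from vehicle could not be checked either.

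With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of the 6 libraries alone, the real split gave the most genes (1 of 10 splits as large) in each comparison below except Longan Arillus high against low, where all 10 splits gave 0. The real value and the highest other split at the high dose against vehicle were 1985 and 2 for Yijin-tang, 2012 and 1 for Liriopis seu Ophiopogonis Tuber, 1676 and 1 for Schisandrae Fructus, 983 and 0 for Longan Arillus, and 5183 and 0 for Zizyphi Semen. In the same order they were 924 and 2, 1819 and 2, 807 and 1, 1595 and 0, and 4567 and 0 at the medium dose, and 1740 and 0, 1614 and 2, 1620 and 3, 1 and 0, and 5262 and 0 at the low dose. For high against low they were 291 and 2, 5 and 4, 92 and 1, 0 and 0, and 316 and 2. Between extracts they were 271 and 2 for set 9 and 27 and 0 for set 10.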

How the results depend on the processing

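The fits without 2 libraries, the library batch term and the tests of differences between dose effects were chosen after the data were seen. Counts below follow the order Yijin-tang, Soshiho-tang, Liriopis seu Ophiopogonis Tuber, Schisandrae Fructus, Longan Arillus and Zizyphi Semen, and between extracts the order of sets 8, 9 and 10. Of 338 named gene results, 173 kept their direction and call under each alternative run for them that was chosen before the data were examined. Of 190 called lists, 105 did. The fits without the 2 libraries and with the batch term are not part of these counts. Without the 2 libraries, 10 named genes and 3 lists turned direction, and 2 and 5 more lost their call. With the batch term as well, 15 named genes and 3 lists turned direction, and 21 and 7 more lost their call. With RLE size factors, 27 of 27 gene counts and 15 of 15 list counts stayed within 1.5 times, and 3 named genes and 2 lists lost their call. A depth of 18.003 to 33.832 M counts limits genes under about 1 CPM.

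Without a low-count filter (37420 genes tested), 23 of 27 gene counts moved by over 1.5 times: 48, 423, 30, 55, 102 and 233 at the high dose, 1, 87, 21, 37, 167 and 541 at the medium dose, 6, 7, 19, 28, 4742 and 486 at the low dose, 16, 116, 0, 1, 1320 and 2 for high against low, and 96, 0 and 1 between extracts. More genes were tested there, which raises adjusted p, and 99 named genes and 10 lists lost their call. By the DESeq2 Wald test 18 counts moved, and the counts were 201, 1172, 111, 342, 391 and 902 at the high dose, 49, 756, 80, 132, 592 and 1366 at the medium dose, 72, 36, 76, 133, 6513 and 1295 at the low dose, 51, 388, 1, 21, 3642 and 19 for high against low, and 313, 35 and 15 between extracts. The cause was not tested, and 2 of 337 named genes lost their call. In fits of only the 2 groups compared, 27 counts moved: 1985, 4959, 2012, 1676, 983 and 5183 at the high dose, 924, 0, 1819, 807, 1595 and 4567 at the medium dose, 1740, 1059, 1614, 1620, 1 and 5262 at the low dose, 291, 1726, 5, 92, 0 and 316 for high against low, and 1706, 271 and 27 between extracts. There the 2 libraries that stood apart enter only the comparisons of their own groups, and 17 named genes lost their call. Replicate numbers as a block were run as an alternative, although libraries of 1 number were paired by the check in 0 of 27 comparisons (correlations of -0.226 to 0.244). With the block, the Schisandrae Fructus high against low count was 4, the other 26 gene counts and 15 list counts stayed within 1.5 times, and 13 named genes and 4 lists lost their call.

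In the fit without the 2 libraries, 25 counts moved: 1307, 3920, 1326, 1667, 2516 and 4034 at the high dose, 525, 172, 667, 786, 3306 and 4990 at the medium dose, 658, 557, 709, 1157, 4583 and 4861 at the low dose, 180, 1734, 0, 280, 16 and 210 for high against low, and 1526, 542 and 131 between extracts. Soshiho-tang medium held 1 library there, with the spread from the other groups. The spread of the fit fell, from a common dispersion of 0.0173 to 0.00244. With the library batch term as well, 22 counts moved: 1597, 4297, 1561, 1958, 692 and 925 at the high dose, 715, 256, 889, 1046, 1313 and 1330 at the medium dose, 850, 700, 990, 1439, 847 and 1041 at the low dose, 235, 1963, 0, 384, 5 and 306 for high against low, and 1722, 667 and 180 between extracts. Genes whose dose effect differed between extracts of a set rose from 51, 0 and 2 to 471, 58 and 25 without the 2 libraries (825, 481 and 3443 at an unadjusted p under 0.05 in edgeR before). Leaving out 1 library, counts ranged from 53 to 69, 294 to 645, 27 to 46, 67 to 101, 56 to 576 and 227 to 304 at the high dose, 3 to 7, 4 to 7983, 15 to 25, 31 to 38, 83 to 798 and 503 to 768 at the medium dose, 3 to 9, 2 to 5, 23 to 28, 30 to 39, 2471 to 8889 and 465 to 650 at the low dose, 15 to 20, 97 to 120, 0, 0 to 1, 3 to 7659 and 2 to 5 for high against low, and 70 to 150, 0 to 2 and 1 to 2 between extracts. Such a fit has fewer samples, and a lone Soshiho-tang library is assumed to vary like the other groups.

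List counts were 18, 19, 14, 17, 9 and 14 against vehicle, 11, 14, 3, 17, 3 and 9 against the low dose, and 19, 14 and 9 between extracts. With an estimated correlation they were 11, 15, 7, 13, 4 and 7 against vehicle, 6, 13, 2, 7, 0 and 4 against the low dose, and 13, 6 and 5 between extracts, and 77 of 190 lists lost their call. Without the 2 libraries, the Liriopis seu Ophiopogonis Tuber and Longan Arillus counts against the low dose were 6 and 6 and that between the extracts of set 10 was 15. With the batch term these were 6, 8 and 15, and Longan Arillus against vehicle had 15. Without a filter, Longan Arillus high against low had 6. The cause was not tested for these. Leaving out 1 library, list counts ranged from 15 to 18, 18 to 21, 14, 17 to 21, 6 to 11 and 13 to 14 against vehicle, 8 to 11, 13 to 16, 1 to 8, 9 to 15, 3 to 4 and 5 to 11 against the low dose, and 18 to 19, 11 to 17 and 8 to 10 between extracts. The median correlation of dose responses was 0.0677 by Spearman and 0.00889 without the 2 libraries, against 0.0232.

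In Longan Arillus high against low, 3 lists turned from lower to higher without the 2 libraries, with the batch term and without low replicate 3. The camera adjusted p values were 3.8e-05, 2.11e-07 and 0.0193 for oxidative phosphorylation, 0.000608, 1.52e-05 and 0.139 for ribosomal proteins and 0.0942, 0.0266 and 0.33 for the proteasome. With an estimated correlation the fit without the 2 libraries gave adjusted p = 0.718 for each of the 3, and 0 of 32 lists were called. Their 10 named members had log2 fold changes in these settings of ATP5ME 0.265, 0.299 and 0.262, NDUFC2 0.0669, 0.0601 and 0.066, NDUFA2 0.103, 0.104 and 0.102, RPS21 0.229, 0.217 and 0.228, RPL36 0.0617, 0.0431 and 0.0607, RPLP2 0.111, 0.0945 and 0.11, PSMA2 0.11, 0.103 and 0.108, PSMB6 0.0461, 0.0472 and 0.0454, PSMB3 0.0381, 0.0448 and 0.0371 and PSMD1 0.0192, 0.00716 and 0.0186. All 3 settings lack low replicate 3. With any 1 library left out, the lowest values were ATP5ME -2.04, NDUFC2 -1.79, NDUFA2 -1.72, RPS21 -1.97, RPL36 -1.91, RPLP2 -1.81, PSMA2 -1.5, PSMB6 -1.23, PSMB3 -1.17 and PSMD1 -1.14, without low replicate 1 or 2, and the smallest list p values 3.37e-11, 8.84e-19 and 0.000302 in the order above. In Zizyphi Semen high against vehicle, the batch term turned MUC6 -0.504, ZBED6 1.27, PWAR5 0.335, TATDN2P2 0.143 and CENPF 0.0334, with no call there and the cause not tested.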

Other observations

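The lists of this part were fixed before the data were examined, and the fit without the 2 libraries that stood apart, used for EPHA2, was added after the data were seen. Feedback genes of the MAPK growth signaling pathway rose in 4 of 14 members in Soshiho-tang high against vehicle, with 0 lower (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000367; n = 2 and 3). They were DUSP4, a MAPK phosphatase (0.38 ± 0.0437), PHLDA1 (0.35 ± 0.0587), and the transcription factors ETV4 (0.33 ± 0.0922) and ETV5 (0.32 ± 0.0645). Against the low dose, PHLDA1 (0.35 ± 0.0649) and DUSP4 (0.28 ± 0.0483) rose (7 adjusted over the list alone; camera adjusted p = 2.22e-06). In the same list EPHA2, an ephrin receptor kinase, fell against vehicle in the high dose of 5 replicated extracts, by -0.39 ± 0.0773 in Yijin-tang, -0.42 ± 0.0773 in Liriopis seu Ophiopogonis Tuber, -0.54 ± 0.0773 in Schisandrae Fructus, -0.43 ± 0.0772 in Longan Arillus and -0.41 ± 0.0772 in Zizyphi Semen (n = 3 each), against the same vehicle libraries. In Soshiho-tang high it was not called (-0.05 ± 0.086, adjusted p = 0.89), but without the 2 libraries that stood apart EPHA2 was called lower at the low dose of all 4 extracts of sets 8 and 9, Soshiho-tang included (mean log2 fold change -0.367). TSC22D3, which encodes the glucocorticoid-induced leucine zipper, rose in Soshiho-tang high (1.52 ± 0.102, adjusted p = 6.29e-14, against vehicle), whereas SGK1, a kinase of the same list of 10 glucocorticoid targets, fell (-0.22 ± 0.0551; 1 higher and 1 lower adjusted over the list alone), and the list had adjusted p = 0.105 with an estimated correlation. Of 22 ribosome biogenesis genes, NOP56, a nucleolar RNA methylation factor (-0.34 ± 0.0852), and ODC1, which starts polyamine synthesis (-0.27 ± 0.0735), fell and 0 rose (2 adjusted over the list alone; camera adjusted p = 0.000512).

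In Yijin-tang high against low, SQSTM1, an autophagy receptor, rose (0.26 ± 0.0593; n = 3 each), 1 of 27 lysosome and autophagy genes with 0 lower (1 adjusted over the list alone), with adjusted p = 0.0887 with an estimated correlation. In Longan Arillus high against vehicle, the lactate transporter gene SLC16A3 (-0.27 ± 0.0698) and the glycolytic enzyme gene GPI (-0.19 ± 0.0506) fell, 2 of 18 glycolysis genes with 0 higher (4 lower and 1 higher adjusted over the list alone), with adjusted p = 0.106 with an estimated correlation.

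In the single Polygalae Radix high library, 14 of 19 heat shock genes were lower by at least 2-fold with 0 higher (median log2 ratio -1.54, percentile 0.01 of random lists), as were 6 of 12 junction and keratin genes (-1.08, percentile 0.09) and 14 of 31 ATF4 genes with 3 higher (-0.82, percentile 0.01). The MAPK feedback genes had a median of 0.48 (percentile 99.94, 0 of 14 by 2-fold). In the single Aucklandiae Radix high library, lysosome and autophagy genes had a median of 0.28 (22 of 27 above the vehicle mean, 0 by 2-fold), above all 10000 random lists. DNA replication genes had a median of -0.45 there (1 of 30 above the vehicle mean, 0 lower by 2-fold), below all random lists. Against the low dose of the same set, the medians in Aucklandiae Radix were 0.325 and -0.339, and in Polygalae Radix -1.71, -1.08, -0.674 and 0.487 in the order above. These libraries have no replicate check.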
